A study of Mus musculus with 6 samples.

How the data were processed

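RNA was measured by sequencing in 6 libraries of mouse embryonic stem cells expressing Tfe3-ERT2, 3 treated with 4-hydroxytamoxifen (4OHT) and 3 with ethanol (EtOH). Per the labels, libraries were made from total RNA with a stranded mRNA kit. The deposited values are raw counts per gene, 1 column per library, with a gene length in bases beside each gene. The authors trimmed, aligned and counted reads with fastp, STAR and featureCounts on mm10 per the submitters' processing notes, which list these tools without roles. The versions, the gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Because the strand setting is not stated, values of genes that overlap others are less certain. Of 198 genes followed by name, 60 share exon bases with another gene model of GENCODE vM21, 50 on the opposite and 14 on the same strand, and 8 share at least 20% of their exon bases.

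The table held 27179 genes, of which 1314 had no symbol and took between 0.411% and 0.478% of the counts of a library. RefSeq for GRCm38 matched 25275 by Entrez Gene identifier. It named 37 of those without a symbol, 13 mitochondrial genes were renamed by identifier, and 1277 kept the identifier alone and stayed in the tests. Positions are those of RefSeq on GRCm38. Libraries had between 16329 and 17000 genes with a count. The transcript Rn45s, a ribosomal RNA precursor, took between 0.484% and 1.30% of the counts. Replicates were checked for duplicates, and every pair differed by more than counting error.

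Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a total of 15, which left 12345. Counts were scaled with TMM factors and compared between groups with edgeR 4.0.16 (robust dispersion, robust quasi-likelihood fit and test) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion was 0.00129, a biological coefficient of variation of 3.59%. Fold changes are unshrunk model coefficients, 4OHT over EtOH, and the SE is the absolute log2 fold change divided by the square root of F. Group means and SDs are of CPM, counts over the library size scaled by TMM factors. The first principal component of log2 CPM (prior count 2) held 66.0% of the variance and separated the groups, and the second held 9.73%.

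The comparison of 4OHT with EtOH is the only one the design gives. The lists of genes (36, main and side), the rule for named genes and the tests were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 35 lists that had at least 3 tested genes. Named under the rule were the MiT/TFE family, 14 further genes given in advance, and the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 2 and no overlap between groups. The rule also took up to 4 called genes with the smallest p from each main list and up to 2 from each side list. It gave 119 genes, and 79 more were followed after their values were seen, among them members of list counts of 5 or fewer, and are marked so where they are named. The replicate numbers were not used as pairs, because the labels do not say that they mark a shared culture or day.

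Alternatives set in advance were DESeq2 size factors, upper quartile factors, no filter and a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0 and limma-voom in place of edgeR, a threshold of 0.01, a minimum of 1.5-fold, leaving out mitochondrial and ribosomal protein genes, camera with an estimated correlation, and fry. Chosen after seeing the data were leaving out Rn45s, thinning every library to the smallest total, and offsets from a smooth trend of counts on GC content and length (loess span 0.4). A screen of 805 Reactome sets of 10 to 300 tested genes, from the copy in fgsea 1.28.0, was also added then. The steps were tested on simulated data with known changes, in which 12218 genes were tested and most of them were left unchanged. They recovered 42.9% of genes changed 1.25-fold, 64% at 1.5-fold, 88% at 2-fold and 100% at 4-fold. Of 171 calls 11 were false (6.43%), and 1 list made to move was recovered. Of the lists that share no gene with it, 0 were called. The simulated genes were drawn independently, so lists of correlated genes were not tested by it. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.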

Results

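RNA-seq libraries were made from mouse embryonic stem cells (mESCs), pluripotent cells kept in culture with serum and the cytokine LIF, which holds back differentiation. The cells carried Tfe3-ERT2, the transcription factor Tfe3 joined to a ligand-binding domain of the estrogen receptor. Such a fusion is held in the cytoplasm until 4-hydroxytamoxifen (4OHT) binds it, after which it enters the nucleus. Tfe3 belongs to the MiT/TFE family, factors known for turning on genes of lysosomes and autophagy. Cells received 4OHT at 1 µg/mL for 48 h (3 libraries) or its ethanol vehicle, EtOH (3 libraries). Total counts in the EtOH libraries were 4984364, 4384615 and 4092877, and in the 4OHT libraries 4648374, 5567195 and 6427880. A count of 3 in 1 library corresponded to between 0.467 and 0.733 CPM (counts scaled to a common library size), a floor that covers counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

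The comparison asks which transcripts differ once 4OHT has been given to cells with the inducible factor. Genes of the lysosome rose in 4OHT: Lamp1, a main glycoprotein of the lysosomal membrane, went from 349 ± 15.9 to 638.5 ± 17.7 CPM (SD, n = 3 each) and the protease gene Ctsd from 243 ± 8.75 to 443 ± 2.70 CPM. Of 26 tested genes of naive pluripotency 18 rose, such as Tfcp2l1 (669 ± 19.7 to 1510 ± 20.3 CPM), and 4 fell (camera adjusted p = 4.4e-05, and adjusted p = 0.059 with an estimated correlation). Genes of the formative state, the next step towards differentiation, fell, and Dnmt3b, a de novo DNA methyltransferase, went from 641 ± 17.6 to 323 ± 4.78 CPM. Of 12345 genes tested with edgeR's quasi-likelihood test, 2643 were higher and 2546 lower in 4OHT at a Benjamini-Hochberg adjusted p under 0.05, and 7156 were not called. Most changes were small, with a median absolute log2 fold change of 0.38 among called genes. At least 1.5-fold were 969 higher and 532 lower genes, and at least 2-fold 355 and 187. The values of the 3 libraries of one group did not overlap those of the other in 6028 genes (48.8%, where chance gives 10%).

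Tfe3 itself (Entrez Gene 209446; GRCm38, the assembly also called mm10, chromosome X, 7762530 to 7775202) was at 1074, 1035 and 1004 CPM in the EtOH libraries and at 832, 836 and 827 CPM in the 4OHT libraries. It fell by 0.32 on the log2 scale (SE 0.03, edgeR adjusted p = 9.8e-19), which is 1.25-fold lower. Its counts pool reads of the endogenous gene and of the fusion transcript, as far as the fusion shares the counted sequence, and the table holds no separate value for either. The related Tfeb was at 31.0 CPM in EtOH and 30.2 in 4OHT (log2 fold change −0.03, edgeR adjusted p = 0.85, and 0.05 on the log2 scale without 4OHT replicate 1). Mitf was at 5.40 and 3.77 CPM (log2 fold change −0.49, edgeR adjusted p = 0.15, and 0.046 without EtOH replicate 2). Tfec had 2 counts in 1 EtOH library and none elsewhere and was not tested. As a list, the MiT/TFE family had 1 lower member, Tfe3, among 3 tested, the same count when adjusted over the list alone (camera adjusted p = 0.19).

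**Figure D1:**
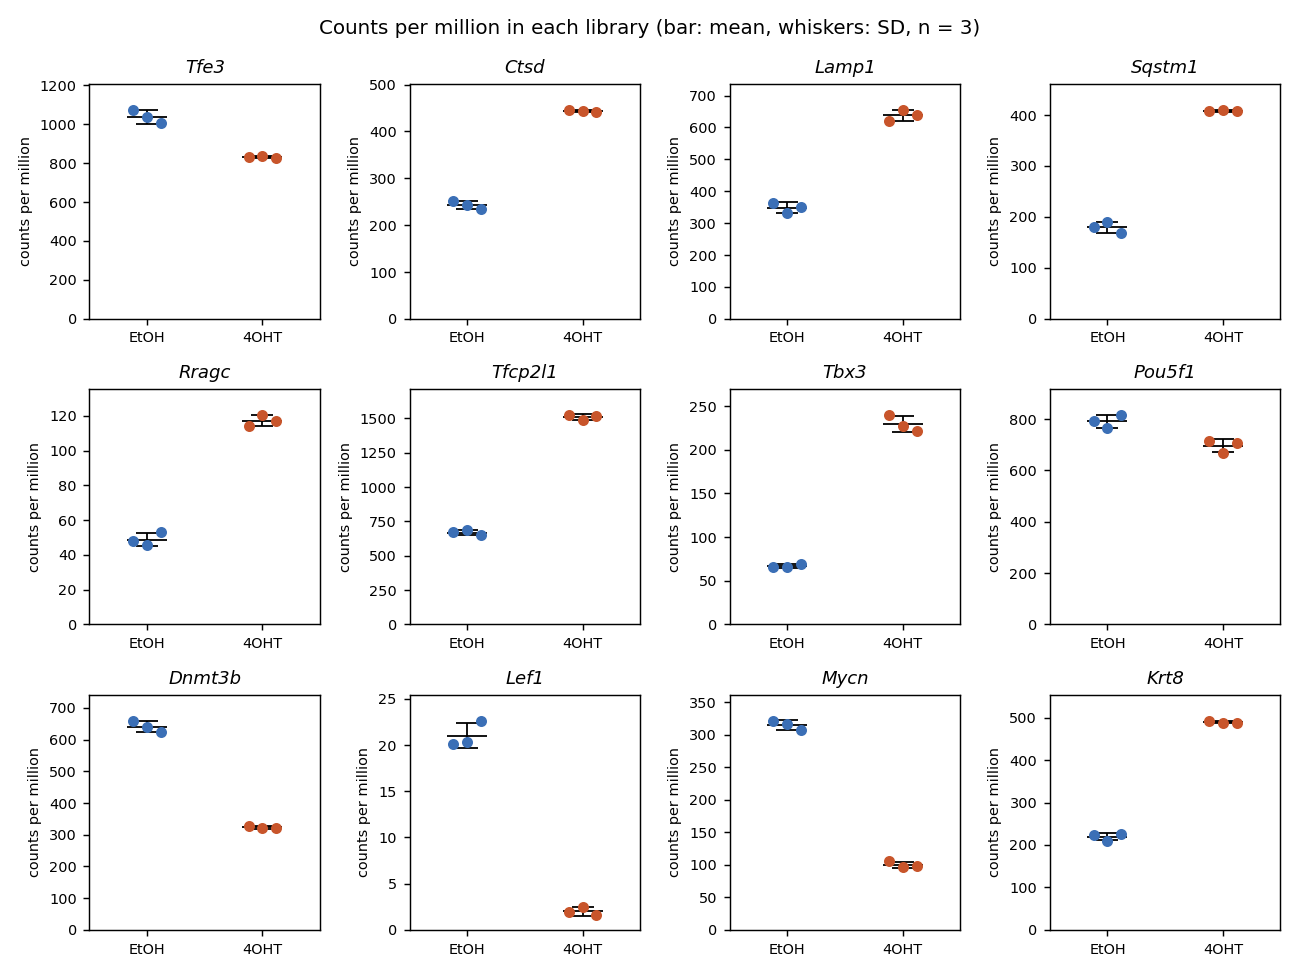
CPM (y axis, from 0) of 12 genes in each library, by group (x axis, EtOH and 4OHT); points are libraries, bars the mean and whiskers the SD (n = 3). Lamp1, Ctsd, Sqstm1, Rragc, Tfcp2l1, Tbx3 and Krt8 lie higher in every 4OHT library, while Tfe3, Pou5f1, Dnmt3b, Lef1 and Mycn lie lower.

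Among genes passing the expression minimum, the largest rises included Stard8 (4.69 to 53.1 CPM, 11.3-fold), Aqp3, a water and glycerol channel (9.72 to 104 CPM, 10.8-fold), and Fabp3, a fatty acid binding protein (chromosome 4, 130308738 to 130315463; 30.2 to 249.7 CPM, log2 fold change 3.04, SE 0.06, edgeR adjusted p = 8.7e-123). The neighbours S100a13 and S100a1, which encode calcium-binding proteins and whose annotated ranges on chromosome 3 overlap at their ends, rose 10.1-fold and 8.28-fold. Itpr2, an inositol trisphosphate receptor, rose 8.90-fold, the transporter gene Slc16a9 7.36-fold and Lrrc15 7.34-fold. The largest falls included Lef1, a transcription factor of the WNT pathway (chromosome 3, 131110297 to 131224357; 21.0 ± 1.39 to 2.01 ± 0.484 CPM, 10.5-fold lower, edgeR adjusted p = 5.1e-36). Vrtn was 8.22-fold lower, Enpp2, which makes lysophosphatidic acid, 6.70-fold lower and the transcription factor Bcl11a 5.32-fold lower. The WNT-responsive factor Sp5 was 4.88-fold lower, the zinc finger factor Zic2 4.66-fold, the cytokine gene Tnfsf11 4.65-fold and Jph4 4.54-fold lower.

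Genes reported elsewhere as targets of MiT/TFE factors rose. Of 22 tested, 21 were higher and none lower, also 21 when adjusted over the list alone, with a median log2 fold change of 0.72 (camera adjusted p = 4.0e-19). Rragc, a GTPase that carries amino acid signals to mTORC1 on lysosomes, rose from 48.8 ± 3.73 to 117 ± 3.17 CPM (2.41-fold, edgeR adjusted p = 1.5e-45). The autophagy receptor gene Sqstm1 (chromosome 11, 50200152 to 50210820) rose from 179 ± 10.3 to 408 ± 1.64 CPM (2.28-fold, edgeR adjusted p = 3.9e-76). Flcn, which encodes folliculin, a regulator of where Tfe3 sits in the cell, rose 1.52-fold, the calcium channel gene Mcoln1 1.76-fold and Rragd 1.25-fold. The member not called was Wipi1, named after its values were seen, with a log2 fold change of −0.04 that became 0.10 without EtOH replicate 3 and 0.00 without 4OHT replicate 3. Gpnmb, a lysosomal glycoprotein gene, was too low to be tested (0.829 CPM in EtOH and 2.34 in 4OHT). Of the listed targets 20 of the 22 tested also stand on other lists here, so the lists are not separate evidence.

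Lysosomal hydrolases rose with them. Of 13 tested lysosomal proteases and cofactors, 11 were higher and none lower, the same when adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 3.0e-14). The cathepsin genes Ctsl (2.28-fold), Ctsb (2.18-fold) and Ctsd (1.82-fold; chromosome 7, 142375910 to 142387827) and Psap, the precursor of the saposins (1.70-fold), were among them. Ctsd shares 34.4% of its exon bases with a gene model on the same strand, and Ctsl overlaps an antisense gene model. Ctsf and Prcp, named after their values were seen, were not called, with log2 fold changes of −0.09 (0.08 without EtOH replicate 3) and −0.08. Among 38 tested glycosidases, lipases and sulfatases, 24 were higher and 2 lower, or 26 and 2 when adjusted over the list alone (median log2 fold change 0.56, camera adjusted p = 2.7e-08). Asah1, the acid ceramidase, rose 1.84-fold, the cholesterol carrier gene Npc2 1.78-fold, Hexa 2.21-fold and the sialidase gene Neu1 2.31-fold. The lower members, named after their values were seen, were the glucuronidase gene Gusb (1.40-fold lower) and Hyal2 (1.23-fold lower, edgeR adjusted p = 0.0097, but 0.056 without EtOH replicate 3).

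Membrane proteins of the lysosome and its proton pump showed the same direction. Of 37 tested genes of lysosomal membrane and positioning, 27 were higher and 2 lower, also when adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 5.7e-10). The tetraspanin gene Cd63 rose from 33.4 ± 3.12 to 194 ± 4.60 CPM (5.82-fold, edgeR adjusted p = 3.3e-102). Lamp1 (chromosome 8, 13159161 to 13175338) rose 1.83-fold and Igf2r, which sorts enzymes to lysosomes, 1.54-fold. The lower members, named after their values were seen, were the sorting receptor gene Sort1 (1.19-fold lower) and Gnptab, needed for the mannose phosphate tag of lysosomal enzymes (1.16-fold lower). DESeq2 called neither (adjusted p = 0.089 and 0.10). Of 18 tested subunits of the V-ATPase, the pump that acidifies lysosomes, 17 were higher, again 17 when adjusted over the list alone (median log2 fold change 0.63, camera adjusted p = 6.5e-13). Atp6v0d1 rose 2.12-fold, Atp6v0b 1.81-fold, Atp6v1a 1.72-fold and Atp6v1b2 1.51-fold. Atp6v0e2, named after its values were seen, was not called, with a log2 fold change of 0.06, or −0.01 without EtOH replicate 1 and −0.04 without 4OHT replicate 1.

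Of 46 tested genes of autophagy, 22 were higher and none lower, or 24 and 1 when adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.00013, and adjusted p = 0.099 with an estimated correlation). The receptor gene Optn rose 2.62-fold, Wdr45 1.87-fold and the kinase gene Ulk1, which starts autophagy, 1.30-fold. Wdr45 shares 24.7% of its exon bases with a gene model on the same strand. The components of mTORC1, the growth kinase complex, and of its amino acid sensing moved both ways. Of 40 tested, 8 were higher and 8 lower, the same when adjusted over the list alone (median log2 fold change 0.04, camera adjusted p = 0.47). The folliculin partners Fnip1 and Fnip2 rose 1.71-fold and 1.74-fold and the mTORC1 inhibitor gene Tsc1 rose 1.63-fold. Among the 8 lower members, Castor1 and Rragb, outside the genes followed by name, had log2 fold changes of −0.63 and −0.59 (edgeR adjusted p = 1.4e-07 and 1.9e-08).

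Amino acid supply is named in the title of the series. Of 43 tested genes of macropinocytosis and endocytosis, routes by which cells take in extracellular protein, 19 were higher and 7 lower, or 22 and 7 when adjusted over the list alone (median log2 fold change 0.13). The list was not called (camera adjusted p = 0.093), though it was without 4OHT replicate 2 (0.037). Pikfyve, a lipid kinase of endosomes, rose 1.39-fold and Nckap1, part of the WAVE actin complex, 1.20-fold. Sdc1, a heparan sulfate proteoglycan, was 1.75-fold lower and the sorting nexin gene Snx5 1.19-fold lower. Among 28 tested amino acid transporters, 6 were higher and 13 lower, also when adjusted over the list alone (median log2 fold change −0.17). That list was not called either (camera adjusted p = 0.10), though it was after a GC and length correction (0.030). The leucine transporter gene Slc7a5 was 1.31-fold lower and the neutral amino acid carrier gene Slc38a2 1.23-fold lower, while Slc38a1 rose 1.29-fold and the creatine transporter gene Slc6a8 1.69-fold.

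Genes of the ATF4 response and of amino acid synthesis fell. Of 40 tested, 22 were lower and 5 higher, the same when adjusted over the list alone (median log2 fold change −0.15, camera adjusted p = 3.5e-05). Psat1, an enzyme of serine synthesis, went from 899 ± 13.4 to 518 ± 18.1 CPM (1.73-fold lower, edgeR adjusted p = 9.4e-63). The proline synthesis gene Aldh18a1 was 1.45-fold lower, and the leucyl-tRNA synthetase gene Lars was 1.44-fold lower. The 5 higher members, named after their values were seen, were the stress factor gene Ddit3 (2.31-fold), Atf5 (1.42-fold), Got1 (1.28-fold), the glutamine synthetase gene Glul (1.18-fold) and Cebpb (1.42-fold). Cebpb had an edgeR adjusted p of 0.014, which was 0.055 without EtOH replicate 1, 0.095 without EtOH replicate 2 and 0.13 without 4OHT replicate 2.

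Genes of naive pluripotency, the state of the early epiblast, rose on balance. Of 26 tested, 18 were higher and 4 lower, or 19 and 4 when adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 4.4e-05, and adjusted p = 0.059 with an estimated correlation). Tfcp2l1 (chromosome 1, 118627923 to 118685168) rose 2.26-fold, Tbx3 (66.7 ± 2.30 to 229 ± 9.17 CPM) 3.44-fold, Tcl1 2.27-fold, Esrrb 1.56-fold and Klf4 1.39-fold. Nanog rose by less, from 258 to 283 CPM (1.10-fold, edgeR adjusted p = 0.0041). The lower members were Dppa3 (2.17-fold lower) and, named after their values were seen, Nr5a2 (1.54-fold lower), Gbx2 (1.52-fold lower) and Fgf4 (1.18-fold lower). Of 15 tested genes of core pluripotency, which naive and later states share, 10 were lower and none higher, also when adjusted over the list alone (median log2 fold change −0.15, camera adjusted p = 0.00081, and adjusted p = 0.059 with an estimated correlation). Pou5f1, which encodes Oct4, was 1.14-fold lower (791 ± 25.4 to 697 ± 25.8 CPM, edgeR adjusted p = 7.8e-07). Utf1 was 1.29-fold lower, Tdgf1 1.28-fold, the epithelial adhesion gene Epcam 1.26-fold and Lin28a 1.25-fold lower. Sox2 was at 555.5 and 549 CPM and was not called (log2 fold change −0.02, edgeR adjusted p = 0.74, and 0.00 on the log2 scale without 4OHT replicate 1).

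Formative and primed genes fell more than any other main list by median. Of 23 tested, 19 were lower and 1 higher, the same when adjusted over the list alone (median log2 fold change −0.99, camera adjusted p = 2.1e-16). The DNA methyltransferase genes Dnmt3a (chromosome 12, 3801559 to 3914443; 217 ± 4.13 to 66.0 ± 0.899 CPM) and Dnmt3b (chromosome 2, 153649411 to 153687730) were 3.29-fold and 1.98-fold lower. Lefty2 and Lefty1, inhibitors of Nodal signalling, were 3.61-fold and 2.68-fold lower. Otx2, a factor of the formative state, was 1.29-fold lower (edgeR adjusted p = 0.011), a call lost without EtOH replicate 3 (0.13), 4OHT replicate 1 (0.082) or 4OHT replicate 2 (0.060). Fgf5 was too low to be tested (1.77 CPM in EtOH and 0.879 in 4OHT). The higher member was Etv4, named after its values were seen (1.19-fold). Of 14 tested WNT targets, 8 were lower and 3 higher, also when adjusted over the list alone (median log2 fold change −0.53, camera adjusted p = 0.012, and adjusted p = 0.099 with an estimated correlation). The cell cycle gene Ccnd1 was 1.77-fold lower beside Lef1 and Sp5. The higher members were Cdx1 (3.32-fold), Bmp4 (2.20-fold) and, named after its values were seen, the ubiquitin ligase gene Rnf43 (2.48-fold).

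**Figure D2:**
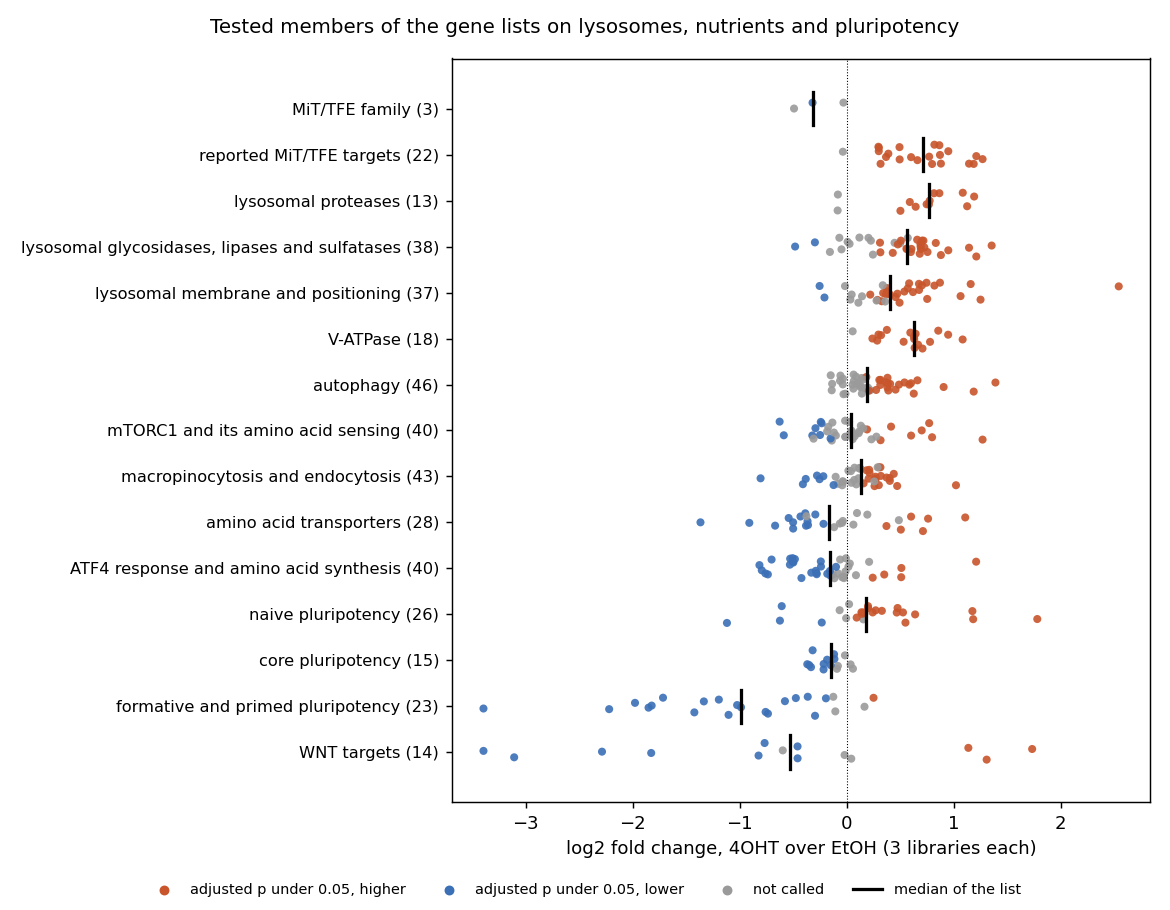
Log2 fold change of 4OHT over EtOH (x axis) of each tested member of the 15 main lists (y axis, number tested in brackets); points are genes, coloured by their call, and bars are list medians. Medians run from −0.99 for formative and primed genes to 0.77 for lysosomal proteases.

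Markers of other cell types did not move as a block. Of 13 tested trophectoderm markers, genes of the outer layer of the blastocyst, 12 were higher and none lower, or 13 when adjusted over the list alone (median log2 fold change 1.16, camera adjusted p = 2.6e-10). The keratin genes Krt8 (220 ± 8.23 to 489.5 ± 2.86 CPM; chromosome 15, 101996711 to 102004342) and Krt18 rose 2.23-fold and 2.31-fold, and Hand1 5.98-fold from 1.54 CPM. The member not called was Ascl2 (log2 fold change 0.37). Other trophectoderm markers were too low to be tested, among them Cdx2 with 14, 12 and 5 counts in EtOH and 6, 8 and 12 in 4OHT, and Elf5 with 1 count in all. Tfap2a had 4 counts in each EtOH library and 11, 5 and 12 in 4OHT, and Plac1 had 4, 1 and 2 against 9, 4 and 3. Ascl2 and these low genes were named after their values were seen. Of 12 tested primitive endoderm markers, 5 were higher and 1 lower, the same when adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.00073, and adjusted p = 0.080 with an estimated correlation). Apoe, a lipid carrier gene also expressed in mESCs, rose from 712 ± 30.5 to 2325 ± 58.5 CPM (3.27-fold, edgeR adjusted p = 2.7e-139), and the basement membrane collagen gene Col4a1 rose 1.94-fold. Col4a2 (2.14-fold), Sparc (1.38-fold) and Lamc1 (1.16-fold) also rose and Lamb1 was 1.47-fold lower, these 4 named after their values were seen. The 6 members not called were Gata4 (log2 fold change 0.14), Sox7 (0.72), Dab2 (0.26), Lama1 (0.04), Cubn (−0.10) and Lrp2 (−0.04), outside the genes followed by name. Of the 23 markers listed, those beyond these 12 did not pass the filter on low counts, among them Gata6, Sox17 and Pdgfra.

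Of 5 tested mesendoderm markers, 3 were higher and 2 lower, the same when adjusted over the list alone (median log2 fold change 1.39, mean 0.24, camera adjusted p = 0.57). The lower ones were T, which encodes Brachyury (22, 25 and 16 counts in EtOH and 0, 5 and 4 in 4OHT), and Wnt3 (3.55-fold lower), and the higher ones Hand1, Eomes (2.62-fold) and Kdr (4, 0 and 4 counts in EtOH and 12, 12 and 21 in 4OHT), where Wnt3, Eomes and Kdr were named after their values were seen. The median of this list was −0.52 without the filter on low counts and −0.24 after thinning. Of 7 tested neurectoderm markers, 3 were lower and none higher, also when adjusted over the list alone (median log2 fold change −0.33, camera adjusted p = 0.011, and adjusted p = 0.099 with an estimated correlation). They were Olig2 (2.13-fold lower), the intermediate filament gene Nes (1.85-fold lower) and, named after its values were seen, Tubb3 (1.60-fold lower). Germ line markers had 1 higher and 4 lower of 11 tested, the same when adjusted over the list alone (median log2 fold change −0.30, camera adjusted p = 0.11). The lower ones were Dppa3, Ddx4 (1.28-fold lower) and, named after their values were seen, Dnd1 (1.46-fold lower) and Tdrd1 (1.75-fold lower), and the higher one, also named so, was Prdm1 (1.36-fold). Calls were lost for Prdm1 without EtOH replicate 1 (0.0502), for Dnd1 without 4OHT replicate 3 (0.054) and for Tdrd1 without EtOH replicate 1 (0.060) or 4OHT replicate 3 (0.089).

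Fibroblast or feeder markers had 3 higher and none lower of 9 tested, also when adjusted over the list alone (median log2 fold change 0.32, camera adjusted p = 0.10). They were the smooth muscle actin gene Acta2 (1.97-fold), Tagln (1.25-fold, with 62.4% of its exon bases under an antisense gene model) and, named after its values were seen, Col5a1 (1.25-fold). The call of Col5a1 was lost after the GC and length correction (0.056) and with DESeq2 (0.11). Macrophage and melanocyte genes had 2 higher and none lower of 5 tested, the same when adjusted over the list alone (median log2 fold change 0.58, camera adjusted p = 0.022, and adjusted p = 0.12 with an estimated correlation). These were Pmel (2.57-fold), a melanosome gene, and Cd68 (2.38-fold), which also stands on the lysosomal membrane list. Of 20 markers of 2-cell-like cells, such as the Zscan4 family of near-identical genes, 19 were in the table and 0 passed the filter on low counts. Without the filter edgeR tested 4, called 0 and found 1 at an unadjusted p under 0.05 (lowest adjusted p = 0.082).

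Genes of lipid synthesis moved slightly. Of 23 tested genes of cholesterol synthesis and SREBP2, 12 were higher and 3 lower, also when adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.035, and adjusted p = 0.12 with an estimated correlation). The call was lost without EtOH replicate 1 (0.089) or 4OHT replicate 1 (0.066). Among the lower ones, named after their values were seen, were Idi1 (1.31-fold lower) and Dhcr7 (1.15-fold lower). The call of Idi1 was lost without EtOH replicate 3 (0.10), 4OHT replicate 2 (0.058) or 4OHT replicate 3 (0.051). That of Dhcr7 was lost without EtOH replicate 1 (0.18), EtOH replicate 2 (0.080), 4OHT replicate 1 (0.091) or 4OHT replicate 3 (0.15). Fatty acid synthesis and storage had 6 higher and 3 lower of 16 tested, the same when adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.025, and adjusted p = 0.20 with an estimated correlation). That call was lost after the GC and length correction (0.10). Scd1 and Elovl6, which desaturate and lengthen fatty acids, rose 1.83-fold and 1.62-fold, while Acly (1.13-fold lower), Fasn (1.12-fold lower) and Acaca (1.17-fold lower), named after their values were seen, fell. The call of Acaca was lost without EtOH replicate 2 (0.099) or 4OHT replicate 2 (0.072).

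Estrogen receptor responsive genes, listed because 4OHT also binds the natural receptor, had 1 higher and 1 lower of 7 tested, the same when adjusted over the list alone (camera adjusted p = 0.47). Their median log2 fold change was −0.10 and their mean 0.04, and camera's direction was down. The retinoic acid receptor gene Rara was 1.59-fold lower. Ret was 1.81-fold higher (edgeR adjusted p = 0.018), a call lost without EtOH replicate 1 (0.14), EtOH replicate 2 (0.16) or 4OHT replicate 3 (0.088). Glycolysis and HIF genes rose on balance, with 14 higher and 5 lower of 25 tested, or 15 and 5 when adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 0.00020, and adjusted p = 0.092 with an estimated correlation). The hypoxia-responsive Bhlhe40 rose 2.85-fold and the glucose transporter gene Slc2a3 1.67-fold. The lower ones, named after their values were seen, were Ldha (1.27-fold lower), Egln3 (1.23-fold lower), Pdk1 (1.12-fold lower), Eno1 and Pkm (each 1.06-fold lower). Calls were lost for Egln3 without EtOH replicate 2 (0.10) and for Pkm without EtOH replicate 3 (0.071) or 4OHT replicate 1 (0.067). For Eno1 the call was lost without EtOH replicate 1 (0.14), EtOH replicate 3 (0.066), 4OHT replicate 1 (0.15) or 4OHT replicate 3 (0.17). Genes of this list and the ribosomal protein genes have many processed pseudogenes, and how shared reads were counted is not stated.

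Nuclear genes of mitochondrial respiration had 4 higher and 6 lower of 30 tested, or 2 and 5 when adjusted over the list alone (median log2 fold change −0.04, camera adjusted p = 0.47). Cox4i1 and Cox5a, subunits of cytochrome c oxidase, each rose 1.26-fold. Sdha (1.07-fold) and Ppargc1b (1.39-fold), named after their values were seen, were also higher. Of the 6 lower ones, Tfam, a factor that maintains mitochondrial DNA, was 1.29-fold lower and Ndufs3 1.19-fold lower, both named likewise. The call of Ndufs3 was lost without EtOH replicate 1 (0.11), EtOH replicate 3 (0.15) or 4OHT replicate 3 (0.24). The call of Sdha was lost without EtOH replicate 2 (0.17), EtOH replicate 3 (0.091), 4OHT replicate 1 (0.19) or 4OHT replicate 2 (0.091). That of Ppargc1b was lost without EtOH replicate 1 (0.13), EtOH replicate 3 (0.23), 4OHT replicate 1 (0.099), 4OHT replicate 2 (0.069) or 4OHT replicate 3 (0.060). Of 10 tested mitochondrially encoded transcripts, 5 were lower and 1 higher, the same when adjusted over the list alone (median log2 fold change −0.14, camera adjusted p = 0.22, but 0.022 without EtOH replicate 2). Among the lower ones were mt-Cytb (1.15-fold lower) and mt-Nd2 (1.12-fold lower), and the GC and length correction ended the call of mt-Nd2 (0.59). The others, named after their values were seen, were mt-Nd1 (1.07-fold lower), mt-Nd4 (1.08-fold lower), mt-Co1 (1.05-fold lower) and the higher mt-Nd3 (1.53-fold). The first 3 of these had positive log2 fold changes after the GC and length correction. The call of mt-Co1 was lost without EtOH replicate 1 (0.0503), EtOH replicate 3 (0.072) or 4OHT replicate 2 (0.11), and that of mt-Nd3 without EtOH replicate 3 (0.067) or 4OHT replicate 1 (0.086).

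Stress lists had members both ways and were not called. The unfolded protein response had 5 higher and 2 lower of 19 tested, also when adjusted over the list alone (median log2 fold change 0.07, camera adjusted p = 0.62). The higher ones were Sel1l (1.30-fold), Calr (1.15-fold) and, named after their values were seen, Edem1 (1.21-fold), Xbp1 (1.18-fold) and Atf6 (1.18-fold), and the lower ones, named likewise, Pdia4 (1.14-fold lower) and Hsp90b1 (1.09-fold lower). Calls were lost for Xbp1 without EtOH replicate 2 (0.068) or 4OHT replicate 3 (0.12) and for Edem1 without EtOH replicate 1 (0.19). NRF2 oxidative stress genes had 7 higher and 6 lower of 18 tested, the same when adjusted over the list alone (median log2 fold change 0.03, camera adjusted p = 0.71). Nfe2l2, which encodes NRF2, rose 1.57-fold and the peroxiredoxin gene Prdx1 was 1.32-fold lower. Among p53 targets and apoptosis genes 4 were higher and 2 lower of 17 tested, or 3 and 2 when adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.77). Bbc3, which encodes PUMA, was 1.62-fold lower and Mdm2 rose 1.24-fold. Plk2 (1.20-fold), Perp (1.16-fold), Ccng1 (1.07-fold) and Pmaip1 (1.25-fold lower) were named after their values were seen. The call of Perp was lost without EtOH replicate 3 (0.084), and that of Ccng1 without EtOH replicate 1 (0.25), EtOH replicate 2 (0.054), 4OHT replicate 1 (0.16) or 4OHT replicate 3 (0.21).

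Cell cycle and proliferation genes fell, with 21 lower and 3 higher of 33 tested, the same when adjusted over the list alone (median log2 fold change −0.16, camera adjusted p = 1.1e-06). Mycn, a growth-promoting transcription factor (chromosome 12, 12936093 to 12941836), went from 315 ± 7.33 to 100.1 ± 4.61 CPM (3.16-fold lower, edgeR adjusted p = 1.3e-94). The higher ones, named after their values were seen, were Ccnd3 (1.42-fold) and the inhibitor genes Cdkn2a (1.64-fold) and Cdkn1b (1.17-fold). The call of Cdkn1b was lost without EtOH replicate 1 (0.11), EtOH replicate 3 (0.057), 4OHT replicate 2 (0.20) or 4OHT replicate 3 (0.074). FGF and ERK feedback genes had 6 higher and 4 lower of 19 tested, or 6 and 5 when adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.47). The phosphatase gene Dusp4 rose 2.71-fold and the early response factor Egr1 was 3.63-fold lower, beside Fgf4 and, named after their values were seen, Etv5 (1.14-fold lower) and Myc (1.22-fold lower). Stress and immediate early genes had 6 higher and 3 lower of 15 tested, also when adjusted over the list alone (camera adjusted p = 0.47). Their median log2 fold change was −0.02, their mean 0.05, and camera's direction was up. The heat shock gene Hspb1 rose 1.48-fold, and Hspa8 (1.12-fold lower) and Zfp36 (1.19-fold lower), named after their values were seen, fell beside Egr1. The call of Zfp36 was lost without EtOH replicate 3 (0.24), 4OHT replicate 2 (0.077) or 4OHT replicate 3 (0.082).

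Ribosomal protein genes fell slightly, with 15 lower and 1 higher of 26 tested, or 16 and 1 when adjusted over the list alone (median log2 fold change −0.12, camera adjusted p = 0.011, and adjusted p = 0.29 with an estimated correlation). The call was lost after the GC and length correction (0.31). Rplp0 was 1.13-fold lower and Rpl7 1.12-fold lower. The higher one, named after its values were seen, was Rps19 (1.07-fold), a call lost without EtOH replicate 1 (0.27), 4OHT replicate 1 (0.064) or 4OHT replicate 2 (0.23). Ribosomal protein genes took between 2.77% and 2.81% of the counts in EtOH and between 2.52% and 2.63% in 4OHT, and mitochondrial genes between 2.38% and 2.52% and between 2.21% and 2.34%.

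**Figure D3:**
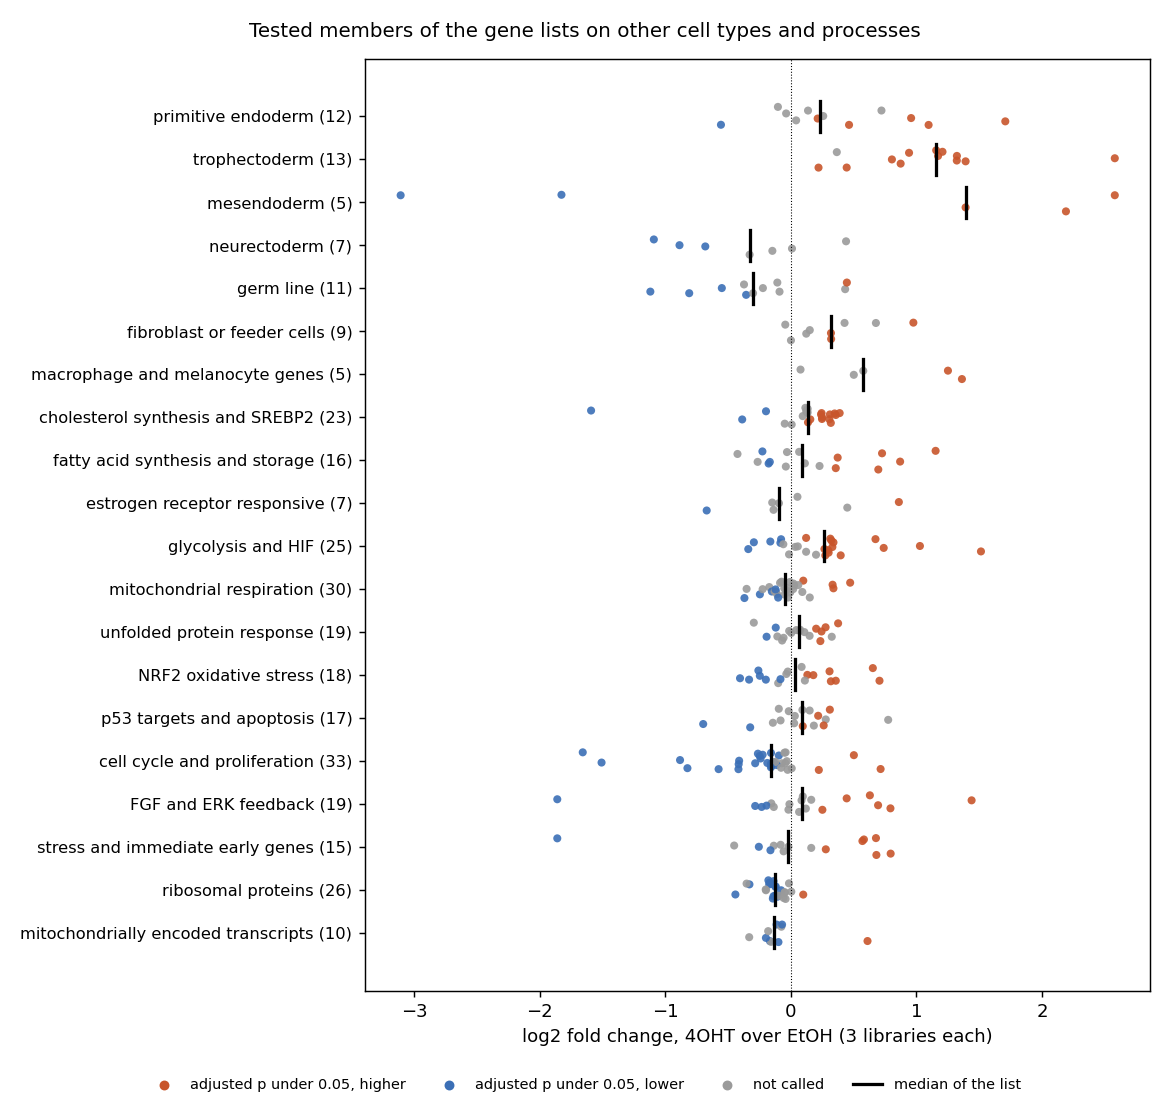
Log2 fold change of 4OHT over EtOH (x axis) of each tested member of the lists on other cell types and processes (y axis, number tested in brackets); points are genes, coloured by their call, and bars are list medians. The trophectoderm list has a median of 1.16 and only the mesendoderm list, with 5 genes on both sides of 0, lies higher, at 1.39.

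Of the 36 lists, 35 had at least 3 tested genes, and camera with its preset correlation called 13 higher and 7 lower. With an estimated correlation 9 calls held: the MiT/TFE targets, the lysosomal proteases, the glycosidases, the lysosomal membrane list, the V-ATPase and the trophectoderm list higher, and the ATF4, formative and cell cycle lists lower. The rotation test fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, called 20 lists higher and 11 lower, and its mixed p-value asks about change in either direction. Scaling by the upper quartile gave a median log2 fold change of all genes of −0.04, against −0.002 with TMM factors, and called 2319 genes higher and 2958 lower. DESeq2 did not call 26 of the 183 called genes followed by name. Among them were Otx2 (DESeq2 adjusted p = 0.10), Ret (0.17), Cebpb (0.14), Dhcr7 (0.21) and Hyal2 (0.088). Lost calls given above are mostly those lost without 1 library, and other settings ended some as well. In simulated data changes under about 1.5-fold were detected in part, with 42.9% of genes changed 1.25-fold and 64% of genes changed 1.5-fold recovered. That simulation changed few genes and gave 171 calls, against 5189 in the data. The adjustment was therefore stricter there, and recovery in the data may be higher.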

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

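Chosen after seeing the data were the settings without Rn45s, thinned to the smallest library and with a GC and length correction; the others were set in advance. Calls at other settings stayed within 1.5 times of 2643 higher and 2546 lower genes except where given here. DESeq2 called 1830 higher and 1623 lower genes, and of its 3453 calls 3417 were shared with edgeR's 5189; the cause was not tested. A minimum of 1.5-fold left 969 and 532, fewer by construction. Leaving out 1 library gave 2306 to 2544 higher and 2129 to 2407 lower genes, and 12 to 14 lists higher and 7 to 8 lower. limma-voom made 5167 calls, 5108 of them shared. Of the lists, camera with an estimated correlation called 6 higher and 3 lower, and fry, which compares with no other genes, 20 and 11. A correlation above the preset 0.01 does not account for every call lost with the estimate. Core pluripotency and neurectoderm lost theirs at estimates of −0.046 and −0.076, and autophagy at 0.044. Lists that kept their calls at estimates below the preset also had much larger camera adjusted p. That of the V-ATPase went from 6.5e-13 to 0.018 at an estimate of 0.006. That of the glycosidases went from 2.7e-08 to 0.021 at −0.009. A larger p with the estimate is therefore not by itself a sign of correlated genes. The cause was not tested further. With the replicate number as a block, 2585 genes were higher and 2497 lower, but nothing pairs the libraries. Deviations of EtOH and 4OHT libraries with the same number from their group means correlated across genes at −0.003, −0.074 and −0.087, where genes are not independent replicates, and no EtOH replicate matched its own number best. Of 3237 values of genes followed by name under alternatives, 3104 kept direction and side of the threshold, 122 lost and 1 gained a call, and 7 uncalled values moved. The sign of 3 called genes was reversed by the GC and length correction: mt-Nd1 to 0.045, mt-Nd4 to 0.013 and mt-Co1 to 0.025 on the log2 scale, where the correction itself moves these genes. Of 523 values of lists, leaving aside estimated correlations and fry, 513 kept their call and camera's direction, 4 lost and 3 gained a call and 3 uncalled ones turned in camera's direction. The median took the other sign in 14 of these values, 0 of them of a list called with the settings of the report. Thinning to the smallest library gave 2480 higher and 2358 lower genes, and the correction 2539 and 2611. The filter left out genes with a few counts per library, such as the 2-cell-like markers, of which the fit without it tested 4 and called 0, with 1 at an unadjusted p under 0.05.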

Other observations

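Camera with an estimated correlation and the lists it is given for were set in advance, while their use in weighing these patterns and all other tests in this part were chosen only after the results were seen. Beyond the lists fixed in advance, a screen of 805 Reactome sets with camera's preset correlation called 56 higher and 202 lower, and 0 with an estimated correlation (lowest camera adjusted p = 0.248, with 159 sets at an unadjusted p under 0.05). With the estimate even the MiT/TFE target list had a camera adjusted p of only 0.0143, against 4.0e-19 with the preset. The 0 calls over 805 sets therefore decide little. After the GC and length correction 41 and 145 were called. Among the higher sets were laminin interactions, the contacts of cells with the basement membrane, with 17 higher and 1 lower of 23 genes (median log2 fold change 0.36, camera adjusted p = 6.9e-06). Nid1 rose 1.97-fold and Hspg2, which encodes perlecan, 1.55-fold, both named after their values were seen. Extracellular matrix organization as a whole had 65 higher and 18 lower of 139 genes.

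Among the lower sets were genes that handle RNA. Of 114 genes of mRNA splicing 64 were lower and 3 higher, with a median log2 fold change of −0.16, and of 22 genes of snRNP assembly 17 were lower and none higher (median −0.28, camera adjusted p = 2.3e-05). Many of the lower snRNP genes also stand in the splicing set, so these sets are not separate evidence. Pabpn1 and Srsf7 were each 1.21-fold lower, and Prmt5 and Clns1a, which act in snRNP assembly, 1.33-fold and 1.34-fold lower. Purine synthesis had 10 lower and none higher of 12 genes (median −0.34), with Gart 1.31-fold and Atic 1.27-fold lower. These 6 genes were named after their values were seen. The 10 lower purine genes include the pseudogene Impdh2-ps beside Impdh2 (log2 fold changes −0.37 and −0.41), both outside the genes followed by name. How reads they share were counted is not stated.

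The first pattern weighed is the rise of 5 lists of lysosomal genes and MiT/TFE targets. The 4OHT libraries were on average deeper, though 4OHT replicate 1 had fewer counts than EtOH replicate 1. With every library thinned to the smallest, 5 of the 5 lists were still called higher, but calls this strong could hardly be lost by thinning. The median log2 fold changes of targets, proteases, glycosidases, membrane list and V-ATPase were 0.72, 0.77, 0.56, 0.40 and 0.63 before thinning. After it they were 0.75, 0.75, 0.53, 0.41 and 0.64, which argues against deeper 4OHT libraries as the cause. After the correction for the gene length and GC trend 5 of 5 were also still called. Entry of Tfe3-ERT2 into the nucleus is a candidate explanation, but 4-hydroxytamoxifen acting apart from Tfe3-ERT2 cannot be told apart from it, since no cells without the fusion were sequenced. A list the drug alone could move, cholesterol synthesis, had an adjusted p of 0.120 with an estimated correlation, which decides nothing.

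The second pattern is the fall of formative genes beside the rise of naive genes, of which the latter has an adjusted p = 0.059 with an estimated correlation. Fewer differentiating cells of every type alike would lower the markers of each, and the median log2 fold change of the trophectoderm list was 1.16, which argues against it as the only cause. The rise of that list was known when this was weighed. Members such as Krt8 and Krt18 were already expressed in EtOH, so a rise within the mESCs could hide a loss of such cells. The neurectoderm list went the other way from the trophectoderm list (median −0.33, 3 lower and none higher), so fewer cells of neurectoderm type only stays open (adjusted p = 0.0988 with an estimated correlation). A shift in the shares of naive-like and formative-like cells also stays open, as the 5 of 42 called members of these lists that moved against it only restate the pattern. Bulk libraries do not tell a change of shares apart from a change within cells.

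The third pattern is the small fall of lists of widely expressed and of core pluripotency genes. For the ribosomal protein list, a gene length and GC trend may account for the call, which is also lost with an estimated correlation (adjusted p = 0.29). The median log2 fold change went from −0.12 (SD 0.113 over members) to −0.06 (SD 0.115) after the correction, and the camera adjusted p to 0.312. The median shrank, but camera does not test against the SD over members. The trend was fitted to each library's deviation from the mean of all libraries. It can therefore also take out part of a real change between groups, and the lost call does not single out a technical trend. For the ATF4, core pluripotency and cell cycle lists 3 of 3 were still called lower after the correction, with medians of −0.18, −0.17 and −0.18. This argues against a gene length and GC trend as the whole cause there, though the core pluripotency call does not hold with an estimated correlation before the correction (adjusted p = 0.059). No biological explanation of these falls was tested.

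The 6 libraries can be split into 3 and 3 in 10 ways, so no share of splits can be under 0.1. The real split called 2643 genes higher and 2546 lower, and the highest of the other 9 splits called 0 in each direction, so 1 split of 10 gave as many. A split and its mirror are one, so for lists the larger direction of each other split was taken, 9 at most. The real split called 13 higher, which 1 split of 10 reached, and 7 lower, which 7 splits of 10 reached in one direction or the other. The 7 is the smaller direction of the real split, set here against the larger direction of the others. In both directions together the real split called 20 lists, and the other 9 splits between 7 and 14. The other splits keep 2 of 3 libraries of a condition together, so part of the difference between conditions remains in them. The rest of that difference widens the spread within their groups, which holds back calls of single genes. Their 0 gene calls were therefore close to built in and say little about chance.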
